A study of Homo sapiens with 8 samples.

How the data were processed

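Poly-A RNA of HepG2 cells was sequenced in 8 libraries, 2 for each of 4 groups: BaP 12 h, BaP 24 h, vehicle 12 h and vehicle 24 h. Per the labels, the 2 libraries of a group came from independent experiments, and cells at 80% confluence received fresh medium with BaP or DMSO. The deposited files, 16 in number, give results per gene and per transcript for each library. Their estimated counts are deposited as RSEM made them, without normalisation, from reads aligned by the authors with Bowtie 0.12.7 and divided between transcripts by RSEM 1.1.7. The deposited fractions are the authors' RSEM estimates of the share of all transcript molecules, corrected for length, and sum to 1 per library. The deposited files also hold posterior mean counts, posterior mean fractions and interval bounds whose level is not given. The authors' notes name edgeR without a version or a test. The annotation was Ensembl release 58; the genome build is not given in the sources used here, so no positions are printed.

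The files held 49733 gene IDs and 142467 transcript IDs, and 26741 gene IDs had a count in any library. Gene names were looked up by Ensembl ID in a reference of gene symbols, and in GENCODE 29 where that reference gave none. Genomic spans, mRNA lengths and GC contents were looked up by ID in GENCODE 29. Names were found for 41044 gene IDs (82.5%), 40589 by gene ID and 455 through their transcript IDs, and these IDs took 96.7% of the counts. Of 616 members of the 25 gene lists, 9 matched no ID. Total counts per library ranged from 2592272 to 16533490. A gene with no count may hold up to 3 counts, which is 1.16 CPM in replicate 1 of BaP 24 h and 0.181 in replicate 2. Such floors and intervals cover counting error only, since reads are not independent molecules.

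Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups (minimum count 10, minimum total count 15), which left 14746, and libraries were scaled by the trimmed mean of M-values. A quasi-likelihood model with robust dispersions was fitted to all 8 libraries with 1 mean per group. The comparisons were BaP against vehicle at 12 h and at 24 h, the difference between these (24 h minus 12 h), and vehicle at 24 h against 12 h. Tests were two-sided, and p was adjusted by Benjamini and Hochberg over the genes of a comparison, with a threshold of 0.05. CPM are depth-scaled counts, computed by edgeR with the scaled library sizes, and levels are means and SDs of 2 libraries. The SE of a fold change is its size divided by the square root of the F statistic. The 12 h and 24 h comparisons used different vehicle libraries.

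Gene lists were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) at a preset correlation of 0.01, with p adjusted over lists and comparisons, again with an estimated correlation, and with fry. Counts adjusted over the list alone used the members' own p values. Transcript usage was tested with edgeR's gene-level F-test on transcripts that held at least 10% of their gene's counts over all libraries, which left 17034 transcripts of 6831 genes. The genes named were chosen by a rule fixed before the data were examined, as were the groups, comparisons, lists and the alternatives named first below. For BaP at each time the rule takes the 10 largest rises and the 10 largest falls among genes that passed, had a name and a mean of at least 5 CPM, and had both BaP libraries on the same side of both vehicle libraries. It takes the 5 largest each way for the difference and for vehicle over time, the 5 genes with the smallest p for usage, up to 4 members with the smallest p per list, and always CYP1A1, CYP1A2, CYP1B1, AHRR, TIPARP, NQO1, AHR, CDKN1A, MDM2 and GDF15. Some genes that the rule takes are not reported here. RASGRF2 was named after its values were seen.

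The labels do not say that a replicate number marks the same experiment in every group, so the fit had no replicate term, and a fit with a replicate block was an alternative. The 2 libraries of a group were correlated across the 7299 genes with a mean log2 CPM over 4, which leaves out genes with lower counts. The correlation was 0.992 (BaP 12 h), 0.974 (BaP 24 h), 0.984 (vehicle 12 h) and 0.992 (vehicle 24 h).

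The alternatives fixed at that point were DESeq2's size factors, no filter on low counts (minimum total count 1), the Wald test of DESeq2 1.42.0, edgeR's exact test, the replicate block, a fit to the libraries of a comparison alone, and leaving out each library in turn. For usage they were DESeq2's size factors, no minimum share, the Simes test, the block and leaving out each library. Chosen after the data were seen were thinning all libraries to 2592234 counts (1 draw), a GC and mRNA length correction per library with mgcv 1.9.3 (13621 genes, 92.4%) with and without the block, RSEM's posterior mean counts for usage, and the split by genomic span, which was known for 13765 of the genes tested (93.3%).

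The tests were tried on simulated data, counts drawn from the mean levels of the vehicle libraries with the fitted dispersions. At 12 h, 28.0% of genes changed by 1.5-fold were recovered, 90.0% at 2-fold, 96.0% at 3-fold and 98.0% at 4-fold, and 4.29% of calls were false. At 24 h, 34.0%, 92.0%, 100% and 100% were recovered and 6.32% of calls were false. The changed genes were drawn from those with a vehicle mean of at least 5 CPM, and all groups were given the same dispersion per gene. The larger spread between the real BaP 24 h libraries (SD 0.32, against 0.17 to 0.25 in the other groups) was therefore not simulated. For usage, with a share moved from 80% to 20%, 38.0% of the changed genes were recovered at 12 h and 42.0% at 24 h, with 16.5% and 16.0% of calls false. For lists of 25 genes, 100% of 20 lists shifted by 0.5 on the log2 scale were recovered and 1 of 80 unchanged lists was called. Smaller shifts of lists and of usage were not tried. The genes of the simulated lists were drawn independently, whereas correlations estimated within the real lists ranged from -0.0868 to 0.908. The list trial therefore does not cover lists whose genes vary together.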

Results

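Poly-A RNA was sequenced from HepG2 cells, a human hepatocellular carcinoma line, exposed to benzo[a]pyrene (BaP) or to its solvent. BaP is a polycyclic aromatic hydrocarbon that activates the aryl hydrocarbon receptor (AHR) and is metabolised to products that bind DNA. The dose was 2 µM and the vehicle was 0.5% DMSO, given for 12 h or 24 h. Each of the 4 groups held 2 libraries from independent experiments. The deposited gene-level estimated counts summed to 8272319 and 12443348 in the BaP 12 h libraries and to 13363783 and 14048067 in the vehicle 12 h libraries. At 24 h they summed to 2592272 and 16533490 with BaP and to 11844661 and 5590972 with vehicle, so replicate 1 of BaP 24 h was the shallowest library. Mitochondrial transcripts took 17.1% to 18.7% of the counts of each library. The log2 difference between the 2 replicates of a group was taken across the 7299 genes with a mean log2 CPM over 4. Its SD was 0.17 (BaP 12 h), 0.32 (BaP 24 h), 0.25 (vehicle 12 h) and 0.18 (vehicle 24 h). Fold changes are given as log2 ± SE with n = 2 libraries per group, levels as CPM (depth-scaled read counts, mean ± SD, n = 2), and every adjusted p is from edgeR's quasi-likelihood test unless another test is named.

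The comparison at 12 h asked which transcripts changed with BaP against the matched vehicle. The largest rise was in CYP1A1 (ENSG00000140465), a cytochrome P450 that oxidises BaP and a classic AHR target, from 5.03 ± 2.17 to 1013 ± 66.2 CPM (log2 7.66 ± 0.24, adjusted p = 1.3e-10). ALDH3A1 (ENSG00000108602), an aldehyde dehydrogenase, rose from 0.971 ± 0.0882 to 32.0 ± 3.29 CPM (log2 5.02 ± 0.25). The aldo-keto reductase AKR1B10 (ENSG00000198074) rose from 31.0 ± 2.20 to 197 ± 0.0643 CPM. The other rises among the 10 largest were in LRRC25 (3.59 ± 0.36), MAP1A (3.46 ± 0.28), NKAIN1 (3.36 ± 0.35), WNT11 (3.02 ± 0.27), AHRR (2.99 ± 0.32), the water and glycerol channel AQP3 (2.59 ± 0.21) and NECTIN4 (2.50 ± 0.23). The largest fall was in SNX29 (ENSG00000048471), from 20.7 ± 0.621 to 0.617 ± 0.543 CPM (log2 -4.89 ± 0.29, adjusted p = 1.9e-08). Other falls among the 10 largest were in the synaptic scaffold gene SHANK2 (-2.85 ± 0.15), BCAS3 (-2.72 ± 0.20), the protein kinase C gene PRKCA (-2.65 ± 0.13), TTC28 (-2.43 ± 0.16), the phosphatase gene PTPRG (-2.36 ± 0.17), the phospholipase C gene PLCB1 (-2.34 ± 0.14), TLN2 (-2.32 ± 0.15) and VPS13B (-2.23 ± 0.21). These 19 genes kept direction and call in every alternative computed at 12 h. Of 14746 genes tested, 503 were higher and 713 lower with BaP at 12 h, of which 153 and 246 changed by over 2-fold. The counts of higher and lower genes were 174 and 250 without BaP 12 h replicate 1, 212 and 351 without BaP 12 h replicate 2, and 335 and 425 without vehicle 12 h replicate 1. Without vehicle 12 h replicate 2 there were 317 higher genes, and DESeq2 called 266. With all libraries thinned to the depth of the shallowest, 212 were higher and 366 lower, and with a GC and mRNA length correction 888 were higher.

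**Figure D1:**
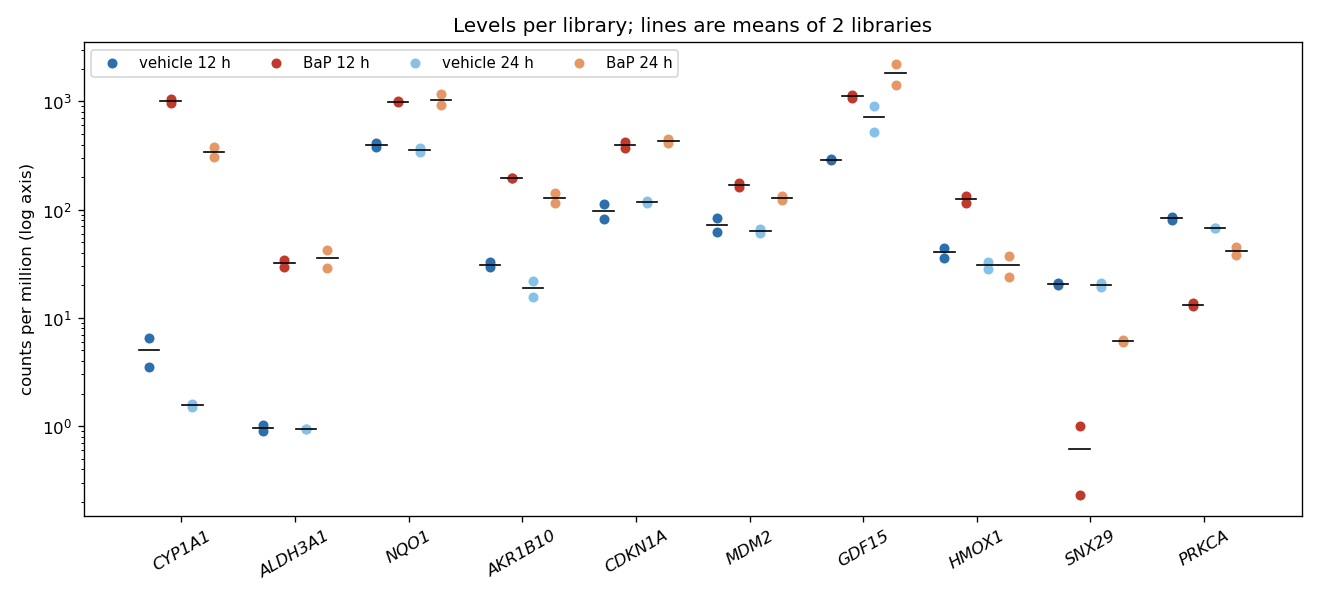
Levels in CPM (log axis) of 10 genes in each of the 8 libraries; points are libraries, coloured by group, and black lines are means of 2 libraries. CYP1A1 averaged 1013 CPM with BaP and 5.03 with vehicle at 12 h, and SNX29 averaged 0.617 CPM with BaP and 20.7 with vehicle.

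Targets of 3 stress-responsive transcription factors rose at 12 h. Of 14 AHR target genes tested, 6 rose and 0 fell (7 and 0 adjusted over the list alone), with a median log2 fold change of 0.65 and a camera adjusted p of 5.2e-08 (adjusted p = 0.044 with an estimated correlation). They included NQO1, a quinone reductase that is also an NRF2 target (395 ± 22.7 to 992 ± 16.4 CPM, log2 1.33 ± 0.15), and CYP1B1, with 38 counts in the BaP libraries and 1 in the vehicle libraries. Scaled by library depth, that ratio was 50.3, with an exact 95% interval of 8.50 to 2038 that covers counting error only. Without BaP 12 h replicate 1 the log2 fold change was 4.88 and the call was lost. CYP1A2 (0.89 ± 0.46, adjusted p = 0.3), TIPARP (0.11 ± 0.22, adjusted p = 0.86) and AHR itself (-0.28 ± 0.16, adjusted p = 0.36) did not pass. Of 36 p53 target genes, 27 rose and 0 fell (30 and 0 adjusted over the list alone, median 0.75, camera adjusted p = 6.9e-20, and adjusted p = 0.011 with an estimated correlation). The cell cycle inhibitor CDKN1A (ENSG00000124762) rose from 97.4 ± 22.2 to 395 ± 36.3 CPM (log2 2.02 ± 0.15). BTG2 (1.41 ± 0.15), the ubiquitin ligase MDM2 (1.21 ± 0.13), the death receptor FAS (1.53 ± 0.17) and the stress cytokine GDF15 (1.95 ± 0.27) also rose. Of 23 NRF2 target genes, 15 rose and 0 fell (19 and 0 adjusted over the list alone, median 0.80, camera adjusted p = 5.8e-18). The camera call was lost with an estimated correlation (adjusted p = 0.084). Members that rose included OSGIN1 (2.27 ± 0.12), the glutathione synthesis gene GCLM (2.38 ± 0.15) and the thioredoxin reductase TXNRD1 (1.39 ± 0.13).

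Members of other lists also passed at 12 h, where 8.25% of all genes tested passed. Of 20 immediate early genes, 5 rose and 0 fell (8 and 1 adjusted over the list alone), with a camera adjusted p of 2.0e-05 (adjusted p = 0.4 with an estimated correlation and 0.1 by fry), and the AP-1 genes FOSL1 (1.60 ± 0.14) and ATF3 (1.38 ± 0.23) were among them. Of 26 apoptosis regulators, 5 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 2.7e-04, and adjusted p = 0.093 with an estimated correlation); FAS, BAX, BBC3, PMAIP1, TNFRSF10A and TNFRSF10B stand in both this list and the p53 list. Of 25 cholesterol synthesis genes, 5 fell and 0 rose, the same counts adjusted over the list alone (median -0.22, camera adjusted p = 6.9e-05, and adjusted p = 0.11 with an estimated correlation). They included the lanosterol synthase LSS (-0.67 ± 0.12, adjusted p = 0.064 without BaP 12 h replicate 1). Of 17 fatty acid synthesis genes, 5 fell and 0 rose (8 and 0 adjusted over the list alone, median -0.28, camera adjusted p = 6.9e-05, and adjusted p = 0.28 with an estimated correlation), among them the lipogenic regulator SREBF1 (-0.59 ± 0.11, adjusted p = 0.071 without BaP 12 h replicate 1). Of 33 mitotic genes, 6 fell and 0 rose (7 and 0 adjusted over the list alone, median -0.20, camera adjusted p = 6.4e-04, and adjusted p = 0.22 with an estimated correlation). CDC20 (-0.51 ± 0.12) and PLK1 (-0.50 ± 0.14) were examples, and their adjusted p became 0.17 and 0.29 without BaP 12 h replicate 1, 0.12 and 0.16 without BaP 12 h replicate 2, and 0.14 and 0.32 without vehicle 12 h replicate 1. Of 41 DNA replication genes, 1 rose and 4 fell (1 and 6 adjusted over the list alone, median -0.10, camera adjusted p = 0.034, and adjusted p = 0.56 with an estimated correlation and 0.19 by fry). MCM3, part of the replicative helicase, fell by 0.51 on the log2 scale, with an adjusted p of 0.22 without BaP 12 h replicate 1 and 0.057 without BaP 12 h replicate 2. Of 26 hepatocyte secreted proteins, 3 fell and 0 rose (4 and 0 adjusted over the list alone, median -0.19, camera adjusted p = 0.003, and adjusted p = 0.5 with an estimated correlation and 0.18 by fry). The fibrinogen chain gene FGA (-0.60 ± 0.13) was one, with an adjusted p of 0.13 without BaP 12 h replicate 1 and 0.1 without BaP 12 h replicate 2.

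**Figure D2:**
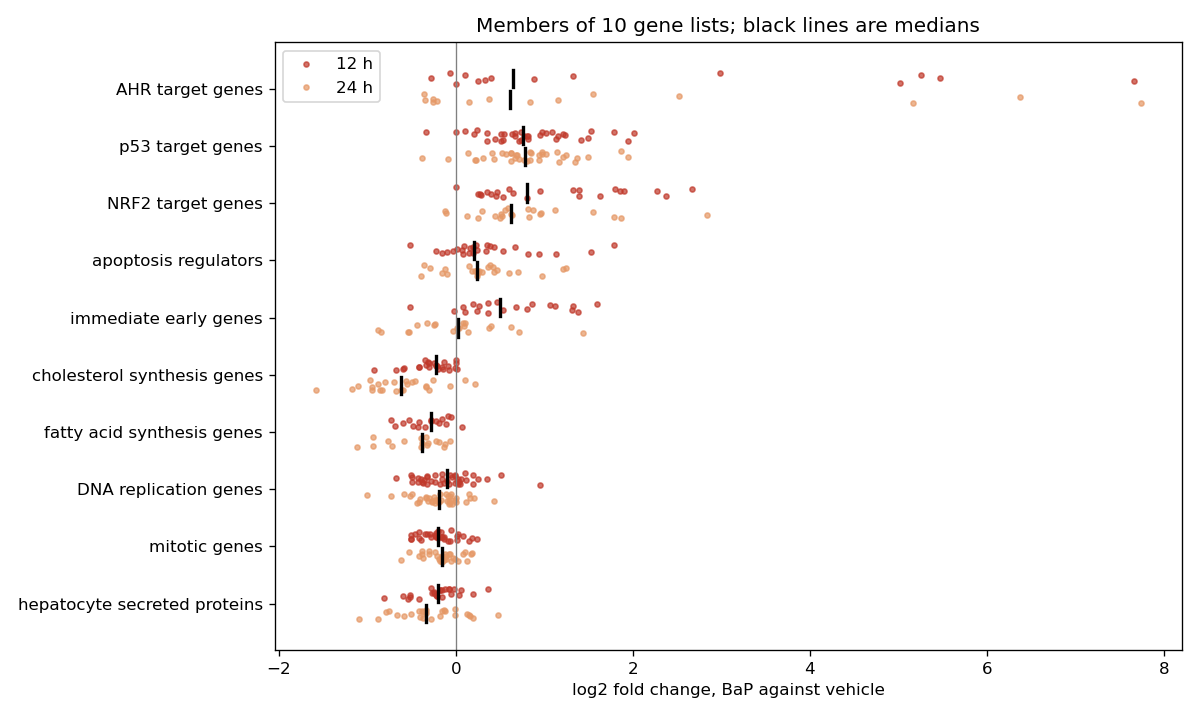
Log2 fold change of BaP against vehicle (x axis) for the tested members of 10 gene lists, at 12 h (red) and 24 h (orange); each point is a gene, black lines are list medians and vertical scatter is random. The median of the p53 target genes was 0.75 at 12 h and 0.79 at 24 h, and that of the cholesterol synthesis genes -0.22 and -0.62.

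Many of the genes that fell at 12 h were long in the genome. The largest falls named above spanned 454 to 891 kb in GENCODE 29, a property looked up after the values were seen. Of the 713 lower genes, 450 spanned over 100 kb and 248 spanned up to 100 kb, against 2355 and 11410 of the genes tested. The median log2 fold change was 0.07 for 6989 genes up to 30 kb, -0.29 for 453 genes of 200 to 300 kb, -0.56 for 269 genes of 300 to 500 kb and -0.91 for 126 genes over 500 kb. In the last bin 65 genes fell and 0 rose. At 24 h the medians in these bins were 0.08, -0.12, -0.21 and -0.33, and 26 of the 126 genes over 500 kb fell. As a set, the 395 genes over 300 kb moved down at 12 h (camera p = 1.7e-42, and p = 0.0046 with an estimated correlation) and at 24 h (camera p = 7.4e-11, and p = 0.053 with an estimated correlation).

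**Figure D3:**
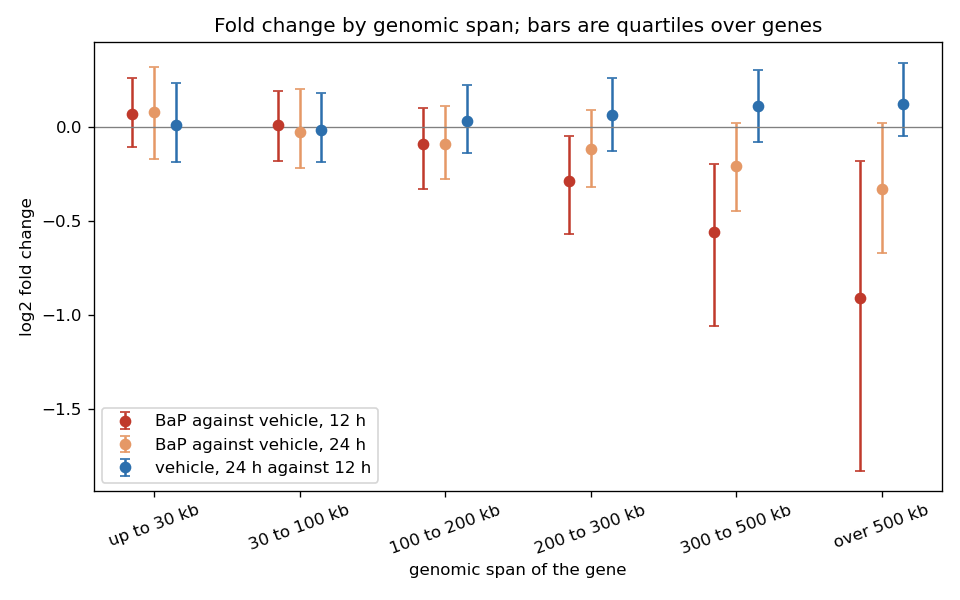
Median log2 fold change (points) with quartiles over genes (bars) in 6 bins of genomic span, for BaP against vehicle at 12 h (red), at 24 h (orange) and for vehicle at 24 h against 12 h (blue). The median over 500 kb was -0.91 at 12 h and -0.33 at 24 h with BaP.

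The comparison at 24 h asked the same question after the longer exposure. CYP1A1 remained the largest rise, from 1.56 ± 0.0800 to 341 ± 49.3 CPM (log2 7.74 ± 0.28, adjusted p = 9.6e-10), followed by ALDH3A1 (5.17 ± 0.29) and AQP3 (4.66 CPM to 49.5 CPM, log2 3.56 ± 0.22). AKR1B10 (2.84 ± 0.16), the prostaglandin reductase PTGR1 (2.83 ± 0.15), NECTIN4 (2.61 ± 0.26), cytoglobin CYGB (1.95 ± 0.15), TP53I3 (1.95 ± 0.15), PDE4C (1.90 ± 0.21) and CDKN1A (1.87 ± 0.15) completed the 10 largest rises. Falls among the 10 largest were in TRAPPC9 (-1.83 ± 0.22), the glypican GPC6 (-1.83 ± 0.16), BCAS3 (-1.75 ± 0.19), LHPP (-1.70 ± 0.26), SNX29 (-1.68 ± 0.23), SLCO4C1 (-1.56 ± 0.30), MYO10 (-1.43 ± 0.18) and the sodium channel gene SCN1A (-1.42 ± 0.22). The call of SLCO4C1 was lost without BaP 24 h replicate 2 (adjusted p = 0.26). With all libraries thinned to the depth of the shallowest, SLCO4C1 (adjusted p = 0.11) and SCN1A (adjusted p = 0.057) lost theirs. Of 14746 genes, 458 were higher and 324 lower, of which 150 and 82 changed by over 2-fold. Without BaP 24 h replicate 1, the shallow library, 1230 were higher and 726 lower. The counts were 167 and 109 without BaP 24 h replicate 2, 95 and 74 without vehicle 24 h replicate 1, and 144 and 92 without vehicle 24 h replicate 2, while DESeq2 called 269 higher. They were 235 and 144 with only the libraries of the comparison and 242 and 165 thinned, and 559 were lower with no filter and 614 with the GC and mRNA length correction.

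Members of the same target lists and of the cholesterol synthesis list passed at 24 h, where 5.30% of all genes tested passed. Of 25 cholesterol synthesis genes, 16 fell and 0 rose (21 and 0 adjusted over the list alone, median -0.62, camera adjusted p = 1.3e-13, and adjusted p = 0.044 with an estimated correlation). LSS fell from 108 ± 3.99 to 56.5 ± 10.3 CPM (-0.97 ± 0.13), and the squalene epoxidase SQLE from 108 ± 2.71 to 56.8 ± 6.11 CPM (-0.95 ± 0.13). Of 17 fatty acid synthesis genes, 5 fell and 0 rose (9 and 0 adjusted over the list alone, median -0.38, camera adjusted p = 3.4e-06, and adjusted p = 0.22 with an estimated correlation), among them the desaturases FADS2 (-0.94 ± 0.14) and SCD (-0.93 ± 0.16). Of 36 p53 target genes, 21 rose and 0 fell (27 and 0 adjusted over the list alone, median 0.79, camera adjusted p = 2.6e-18, and adjusted p = 0.011 with an estimated correlation), including TP53I3, the DNA damage recognition gene DDB2 (0.94 ± 0.12) and MDM2 (1.02 ± 0.14). GDF15 rose by 1.35 ± 0.27, with an adjusted p of 0.019 that became 0.29 without BaP 24 h replicate 2, 0.068 without vehicle 24 h replicate 1 and 0.06 with the GC and mRNA length correction. Of 23 NRF2 target genes, 14 rose and 0 fell (18 and 0 adjusted over the list alone, median 0.63, camera adjusted p = 1.2e-12, and adjusted p = 0.1 with an estimated correlation), including AKR1C1 (1.87 ± 0.20) and TXNRD1 (1.12 ± 0.13). Of 14 AHR target genes, 5 rose and 0 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.002, and adjusted p = 0.11 with an estimated correlation). Their median was 0.61, or 0.26 with CYP1B1 and SERPINB2, which had no counts in the vehicle 24 h libraries, set to their bound against 3 counts over the group. NQO1 (1.55 ± 0.15) and CYP2S1 (0.84 ± 0.13) were among the rises. CYP1A2 (0.15 ± 0.51, adjusted p = 0.92), TIPARP (-0.26 ± 0.26, adjusted p = 0.64) and AHR (-0.21 ± 0.16, adjusted p = 0.52) did not pass, and CYP1B1, with 1 count with BaP and 0 with vehicle, could not be compared at this depth. AHRR had a log2 fold change of 1.16 ± 0.37 (adjusted p = 0.085) and did not pass. It passed with no filter (adjusted p = 0.046), by edgeR's exact test (0.03), with the replicate block (0.033) and with the GC and mRNA length correction (0.034).

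Of 26 apoptosis regulators, 4 rose and 0 fell at 24 h (7 and 0 adjusted over the list alone, median 0.25, camera adjusted p = 4.9e-04, and adjusted p = 0.093 with an estimated correlation), and FAS was one (1.21 ± 0.20, adjusted p = 0.066 without BaP 24 h replicate 2). Of 20 immediate early genes, 1 rose and 0 fell, the same counts adjusted over the list alone. This was FOSL1 (1.44 ± 0.15), and the list's median was 0.03 where camera gave the direction down (adjusted p = 0.89). FOS (-0.88 ± 0.31, adjusted p = 0.15) and EGR1 (-0.54 ± 0.16, adjusted p = 0.08) did not pass. Both were called lower with no filter (adjusted p = 3.6e-04 and 0.0013), by the exact test (0.015 and 0.03) and with the replicate block. They were also called lower without BaP 24 h replicate 2, and EGR1 was called lower thinned (0.033). Of 26 hepatocyte secreted proteins, 3 fell and 0 rose (1 higher and 8 lower adjusted over the list alone, median -0.33, camera adjusted p = 1.2e-04, and adjusted p = 0.4 with an estimated correlation and 0.1 by fry), and the apolipoprotein APOC3 fell by 0.88 on the log2 scale. Of 41 DNA replication genes, 3 fell and 0 rose, the same counts adjusted over the list alone (median -0.19, camera adjusted p = 2.6e-04, and adjusted p = 0.4 with an estimated correlation and 0.073 by fry). They were the helicase genes MCM2 (-0.73 ± 0.12, adjusted p = 0.055 without vehicle 24 h replicate 1), MCM4 (-0.58 ± 0.13) and MCM5 (-0.52 ± 0.13). The adjusted p of MCM4 and MCM5 became 0.098 and 0.12 without BaP 24 h replicate 2, 0.18 and 0.32 without vehicle 24 h replicate 1, and 0.08 and 0.066 without vehicle 24 h replicate 2, and that of MCM5 0.071 with only the libraries of the comparison and 0.081 thinned. Of 33 mitotic genes, 1 fell and 0 rose, the same counts adjusted over the list alone (median -0.15, camera adjusted p = 0.003, and adjusted p = 0.28 with an estimated correlation). This was CENPF (-0.53 ± 0.12), with an adjusted p of 0.18 without BaP 24 h replicate 2, 0.09 without vehicle 24 h replicate 1, 0.18 without vehicle 24 h replicate 2 and 0.067 with only the libraries of the comparison. Among markers of other cell types, the smooth muscle actin gene ACTA2 rose from 48.4 ± 2.91 to 97.1 ± 2.08 CPM at 24 h (1.00 ± 0.12, adjusted p = 1.3e-04). The collagen gene COL1A1 did not pass (-1.90 ± 0.83, adjusted p = 0.31) but was called lower by the exact test (adjusted p = 0.0064) and with the replicate block. The median of the 3 fibroblast and stellate cell markers was -0.41. CD14, a monocyte marker, rose from 2.10 ± 0.210 to 6.34 ± 1.11 CPM (1.54 ± 0.32), with an adjusted p of 0.17 without vehicle 24 h replicate 1, 0.055 without vehicle 24 h replicate 2 and 0.075 by DESeq2.

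The overlap of the calls at the 2 times was counted next, and each time had its own vehicle libraries. In both, 183 genes were higher and 175 lower, where independent lists would share 15.6 and 15.7. One-sided Fisher's exact p was 1.7e-155 and 2.4e-147 over 14746 genes. This test treats genes as independent, and both comparisons come from the same fit with the same spread estimate per gene. Genes measured with little spread can therefore pass more easily at both times, which the numbers for independent lists leave out. The shared genes were 36.4% of those higher at 12 h and 24.5% of those lower at 12 h, and 40.0% and 54.0% of those at 24 h. RASGRF2, named here because it was the single gene called in opposite directions, fell by 0.52 on the log2 scale at 12 h and was 0.47 ± 0.11 higher at 24 h. The fold changes at the 2 times were correlated across the 7299 genes with a mean log2 CPM over 4, which are not independent replicates. Pearson's r was 0.59 and Spearman's rho 0.51. DESeq2's calls shared 223 genes, against 358 for both directions together here.

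**Figure D4:**
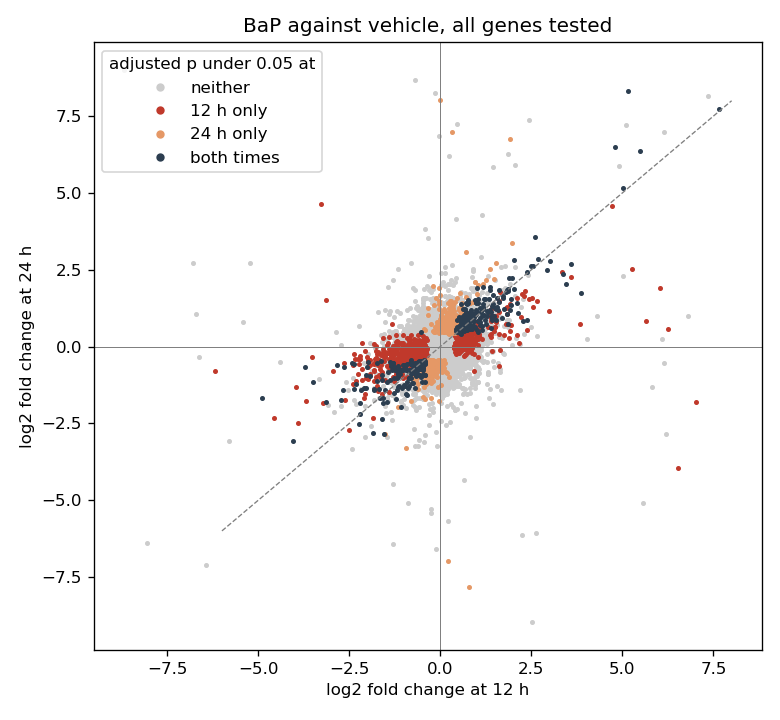
Log2 fold change of BaP against vehicle at 12 h (x axis) and 24 h (y axis) for the 14746 genes tested; each point is a gene, coloured by the time at which its adjusted p passed, and the dashed line marks equal changes. Of the calls, 183 higher and 175 lower genes were shared, and grey points far from the centre are genes with few counts.

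The difference between the 2 responses was tested directly. The 5 largest differences above 0 were in genes that fell at 12 h, among them SNX29 (3.21 ± 0.41, adjusted p = 9.1e-04), SHANK2 (2.24 ± 0.20), PITPNC1 (2.24 ± 0.35) and DIAPH2 (2.12 ± 0.38). HMOX1, a heme oxygenase and NRF2 target, was at 125 ± 11.5 CPM with BaP and 40.3 ± 5.87 with vehicle at 12 h, but at 30.7 ± 9.69 and 30.6 ± 2.90 CPM at 24 h (difference -1.75 ± 0.25, adjusted p = 0.0039, or 0.057 without vehicle 24 h replicate 1). GCLM (-1.51 ± 0.23), OSGIN1 (-1.46 ± 0.17), ATOH8 (-1.38 ± 0.28) and the antisense RNA AC005540.1 (-1.71 ± 0.35) had the other largest differences below 0. AC005540.1 had an adjusted p of 0.032, and its counts cannot be told from those of the opposite strand because the strand used in counting is not given in the sources used here. In total 80 genes passed, 68 above 0 and 12 below 0. Of the 68, 62 were called lower at 12 h, and 57 of the 67 with a known span exceeded 200 kb. The 12 h fold change is subtracted in the difference, so a fall at 12 h in itself raises it. The total was 34 without BaP 12 h replicate 1, 50 without BaP 12 h replicate 2, 348 without BaP 24 h replicate 1, 52 without vehicle 12 h replicate 1, 28 without vehicle 24 h replicate 1 and 45 without vehicle 24 h replicate 2. It was 240 with no filter, 215 with the GC and mRNA length correction and 41 thinned. CYP1A1 (0.08 ± 0.39, adjusted p = 0.97), CDKN1A (-0.15 ± 0.21, adjusted p = 0.87) and SQLE (-0.73 ± 0.18, adjusted p = 0.092) were not shown to differ between the times. DIAPH2, ATOH8 and AC005540.1 lost the call by DESeq2 (adjusted p = 0.1, 0.28 and 0.23), and also without BaP 12 h replicate 1 (0.12, 0.19 and 0.14), without BaP 24 h replicate 2 (0.086, 0.23 and 0.31) and without vehicle 24 h replicate 1 (0.1, 0.31 and 0.18). ATOH8 and AC005540.1 lost it without BaP 12 h replicate 2 (0.094 and 0.17), vehicle 12 h replicate 1 (0.059 and 0.11), vehicle 12 h replicate 2 (0.082 and 0.071) and vehicle 24 h replicate 2 (0.099 and 0.15) as well. Thinned, SNX29 (adjusted p = 0.17), PITPNC1 (0.058), GCLM (0.15), ATOH8 (0.53) and AC005540.1 (0.35) lost the call.

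The vehicle groups at 24 h and 12 h gave the change over time without BaP. The immediate early genes FOS (1.96 ± 0.482 to 26.5 ± 5.51 CPM, log2 3.72 ± 0.37) and EGR1 (2.24 ± 0.17) rose, as did DEPP1 (2.18 ± 0.20), ROBO4 (2.18 ± 0.32) and the secreted binding protein gene IGFBP1, from 364 ± 4.62 to 1630 ± 314 CPM (2.16 ± 0.17, adjusted p = 7.0e-06). FAM111B (-1.20 ± 0.29), GPD1 (-1.13 ± 0.22), GFOD1 (-1.11 ± 0.23), MICAL2 (-1.03 ± 0.25) and KISS1R (-1.02 ± 0.20) had the largest falls. In total 334 genes were higher and 149 lower at 24 h, 483 together. The total was 229 without vehicle 12 h replicate 1, 232 without vehicle 12 h replicate 2, 185 without vehicle 24 h replicate 1 and 87 without vehicle 24 h replicate 2. It was 805 with no filter, 786 by the exact test, 853 with only the libraries of the comparison, 1163 with the GC and mRNA length correction and 268 thinned. FAM111B, GPD1, GFOD1, MICAL2 and KISS1R lost the call without vehicle 24 h replicate 1 (adjusted p = 0.052, 0.1, 0.11, 0.27 and 0.15) and without vehicle 24 h replicate 2 (0.33, 0.1, 0.14, 0.23 and 0.097). Without vehicle 12 h replicate 1 the adjusted p was 0.1 for FAM111B, 0.051 for GPD1, 0.1 for MICAL2 and 0.068 for KISS1R, and without vehicle 12 h replicate 2 it was 0.12 for FAM111B, 0.054 for GFOD1 and 0.091 for MICAL2. By DESeq2 it was 0.093 for FAM111B, 0.063 for GFOD1 and 0.2 for MICAL2, and thinned it was 0.17 for GPD1, 0.13 for GFOD1, 0.21 for MICAL2 and 0.057 for KISS1R.

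Transcript usage, the division of a gene's counts between its transcripts, was tested in 6831 genes. At 12 h, 21 genes were called with BaP, and the 5 with the smallest p were METTL7B, STK11IP, MAP3K7, RTCB and ESYT1. In METTL7B, transcript ENST00000307755 held 100% of the gene's counts with BaP and 1.08% with vehicle, and in MAP3K7, a kinase of stress signalling, ENST00000369329 held 53.3% and 24.7%. At 24 h, 63 genes were called, led by PPP4R1, RNF41, STK11IP, STARD3NL and RNF111, and 20 genes were called between the vehicle groups. In 19 of the 21 genes at 12 h and 34 of the 63 at 24 h, a transcript went from at least 10 counts in each library of one group to under 1 count in each library of the other. In 16 of the 21 and 36 of the 63, RSEM's own intervals for the transcripts overlapped throughout. With the posterior mean counts of the same files, 1 gene was called at 12 h and 18 at 24 h, of which 1 and 3 were the same genes. MAP3K7 was the gene that remained at 12 h (adjusted p = 0.021). By the Simes test 12 genes were called at 12 h and 22 at 24 h, and with the replicate block 2 and 33. The 12 h count was 43 without BaP 12 h replicate 2. The 24 h count was 507 without BaP 24 h replicate 1, 642 without BaP 24 h replicate 2 and 154 without vehicle 24 h replicate 1.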

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

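The tests that weigh explanations here were chosen after the results were seen. For the GC and mRNA length correction, the comparison of long and short transcripts and its controls, the outcomes that would decide were set down before those values were seen. For 80 genes the response to BaP differed between 24 h and 12 h by a direct test of the difference (edgeR), and 16 of them are named in the text. Differences are log2 ± SE, 24 h minus 12 h, with 2 libraries per group.

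Among the genes that passed this test, those called lower at 12 h had differences above 0. The 12 h fold change is subtracted in the difference, so this direction is partly built in. Those named were SNX29 (3.21 ± 0.41), SHANK2 (2.24 ± 0.20), PITPNC1 (2.24 ± 0.35), DIAPH2 (2.12 ± 0.38), PRKCA (1.99 ± 0.18), PLCB1 (1.93 ± 0.19), TTC28 (1.91 ± 0.21), MICAL2 (1.86 ± 0.39), PTPRG (1.78 ± 0.23), VPS13B (1.65 ± 0.29) and TLN2 (1.10 ± 0.22). At the depth of the shallowest library the calls of SNX29 (adjusted p = 0.17) and PITPNC1 (adjusted p = 0.058) were lost. DIAPH2 lost its call without BaP 12 h replicate 1 (adjusted p = 0.12), without BaP 24 h replicate 2 (adjusted p = 0.086) and without vehicle 24 h replicate 1 (adjusted p = 0.1).

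Among the genes that passed this test, those called higher at 12 h had differences below 0, which is partly built in for the same reason. HMOX1, a heme oxygenase, had a difference of -1.75 ± 0.25. Without vehicle 24 h replicate 1 the difference was -1.63 and the call was lost. GCLM (-1.51 ± 0.23) lost its call at the depth of the shallowest library (adjusted p = 0.15), and OSGIN1 (-1.46 ± 0.17) did not lose it in any alternative run. ATOH8 (-1.38 ± 0.28) and AC005540.1 (-1.71 ± 0.35) kept the call in 1 of the 8 fits without a library, that without BaP 24 h replicate 1. In the other fits the adjusted p of ATOH8 and AC005540.1 was 0.19 and 0.14 without BaP 12 h replicate 1, 0.094 and 0.17 without BaP 12 h replicate 2, 0.23 and 0.31 without BaP 24 h replicate 2, 0.059 and 0.11 without vehicle 12 h replicate 1, 0.082 and 0.071 without vehicle 12 h replicate 2, 0.31 and 0.18 without vehicle 24 h replicate 1, and 0.099 and 0.15 without vehicle 24 h replicate 2. Thinned it was 0.53 and 0.35.

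The fall of genes with a long genomic span at 12 h was weighed first, and 11 of these 16 genes span over 200 kb. The median log2 fold change of genes over 300 kb lay 0.72 below that of genes up to 30 kb (a gap of -0.72), and a GC and mRNA length correction left a gap of -0.62, so such a bias is not the whole cause. The same gap, taken on the per-gene difference of the 2 replicates of a group, was 0.17 at most. Taken on each library's difference from the mean of the 4 vehicle libraries, it was -0.84 and -0.64 in the BaP 12 h libraries. Every vehicle library lay above these (-0.14 to 0.07), though the vehicle values are centred by that reference. The gap therefore did not rest on a single BaP library. A difference in preparation shared by both BaP 12 h libraries cannot be told from BaP here. A candidate explanation is an obstacle to elongation, such as DNA adducts, which long genes meet more often. Transcripts of the same gene were compared on posterior mean counts. The sign flips treat genes as independent, though all were measured in the same libraries, so p does not measure the spread between experiments. In 734 genes over 100 kb, the transcript with the longest span changed by -0.19 more at 12 h than that with the shortest (median, permutation p = 1.0e-04, the smallest that 10000 sign flips can give). Between the vehicle groups this difference was -0.09 (permutation p = 0.013). In 1039 genes up to 30 kb it was -0.15 with BaP at 12 h (permutation p = 1.0e-04) and -0.07 between the vehicle groups. At 24 h, where the gap by span was -0.32, it was -0.22 in the genes over 100 kb and -0.20 in those up to 30 kb (permutation p = 1.0e-04 for both). The transcript test therefore cannot tell an obstacle to elongation from a loss of longer-reaching transcripts that is not particular to long genes or to BaP, and changes in RNA stability were not tested.

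The number of genes that passed was lower at 24 h (782) than at 12 h (1216). With all libraries at equal depth the calls were 578 at 12 h and 407 at 24 h, a ratio of 1.42, which argues against depth alone. Without the shallow BaP 24 h replicate 1 the 24 h calls were 1956. Leaving out BaP 24 h replicate 2 also removes the spread between the 2 BaP 24 h libraries. Fewer genes then passed in both directions than in the full fit. That fit keeps only the shallow BaP 24 h library, so depth may account for its lower number. It therefore cannot speak against the spread. The 12 h calls were not counted without a 24 h library, so 1956 and 1216 come from different fits. Whether the lower number rests on that spread therefore cannot be told from these fits. The numbers of calls are therefore no measure of a weaker response at 24 h.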

How the results depend on the processing

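Named results were recomputed under each alternative; thinning, the GC and mRNA length correction and RSEM's posterior means were chosen after seeing the data. Over 250 results for single genes, 772 of 1036 fits without a library gave the same direction and call, 239 lost the call, 17 gained it and 8 changed sign; of 2214 results of other alternatives, the numbers were 2000, 116, 97 and 1. Each value that changed sign had not passed. Over the fits without a library, TIPARP at 12 h ranged from -0.13 (without vehicle 12 h replicate 1) to 0.40. At 24 h, the fit without BaP 24 h replicate 2 gave 1 end of the ranges of CYP1B1 (0.00 to 2.85), TIPARP (0.11 to -0.43), RPS13 (-0.07 to 0.69), RPL30 (-0.10 to 0.61), RPL38 (-0.08 to 0.58) and RPL19 (-0.00 to 0.47), and that without vehicle 24 h replicate 1 an end of that of CYP1A2 (-0.19 to 0.50). Thinned, FANCC at 24 h was 0.02. Of 50 list results, fry gave 38 the same, lost 7 calls and gained 3, and it gave the other direction for the immediate early genes (adjusted p = 0.87) and the fibroblast and stellate cell markers (adjusted p = 0.18) at 24 h. With an estimated correlation 31 of 50 list results were the same and 19 lost the call, and with the replicate block 50 of 50 were the same. Some lost calls were in lists whose estimated correlation was below the preset 0.01. These were the AHR targets at 24 h (0.000568), the apoptosis regulators at both times (-0.00420), and 2 lists at 12 h. The 2 were the heat shock genes (-0.000257) and the inflammatory and acute phase genes (-0.0135). Their losses therefore do not show members that vary together.

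Genes higher with BaP at 12 h numbered 266 by DESeq2, 212 thinned, 888 with the GC and mRNA length correction and 926 with that and the block; genes lower with BaP at 12 h numbered 366 thinned. Genes higher with BaP at 24 h numbered 269 by DESeq2, 235 with only the libraries of the comparison and 242 thinned. Genes lower with BaP at 24 h numbered 559 with no filter, 144 with only the libraries of the comparison, 165 thinned, 614 with the GC and mRNA length correction and 645 with that and the block. For the difference between times these were 240 with no filter, 41 thinned, 215 and 243. For vehicle over time they were 805 with no filter, 786 by edgeR's exact test, 853 with only the libraries of the comparison, 268 thinned, 1163 and 1219. Usage calls at 12 h and 24 h numbered 2 and 33 with the block, 12 and 22 by the Simes test, and 1 and 18 with posterior mean counts. DESeq2's calls at both times shared 223 genes. Thinning leaves fewer counts; the cause was not tested for the other alternatives.

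Leaving out a library leaves an arm with 1 library, assumed to vary like the other groups. Over these fits genes higher at 12 h ranged from 174 to 335, lower at 12 h from 250 to 566, higher at 24 h from 95 to 1230, lower at 24 h from 74 to 726, differing between times from 28 to 348, and vehicle over time from 87 to 232. Usage calls ranged from 24 to 43 at 12 h and from 60 to 642 at 24 h. The labels do not say that a replicate number marks the same experiment in every group. The replicate differences of groups with the same numbers were correlated across the 7299 genes with a mean log2 CPM over 4. For BaP and vehicle r was 0.42 at 12 h and 0.06 at 24 h. Between the times it was -0.24 for BaP and -0.04 for vehicle. It was 0.02 for BaP 12 h and vehicle 24 h, and -0.07 for BaP 24 h and vehicle 12 h. With the replicate block 511 genes were higher and 718 lower at 12 h, 431 and 307 at 24 h, and the genes over 300 kb had p = 0.03 at 24 h with an estimated correlation. Beyond usage, the block changed the calls of AHRR at 24 h (adjusted p = 0.033), AC005540.1 in the difference (0.055), FGG at 12 h (0.052), CD14 at 12 h (0.057), COL1A1 at 12 h (-0.96, 0.0031) and 24 h (-1.47, 0.0021), and, at 24 h, HSPA5 (0.059), PDIA4 (0.064), EGR1 (-0.56, 0.042), FOS (-1.03, 0.023) and HBA1 (0.077), and no other named call. With the GC and mRNA length correction and the block, MDM2 (0.79, adjusted p = 0.059), H4C3 (0.051) and HBA1 (0.064) lost the call at 24 h, and H4C3 (0.1) at 12 h. The exact test and the fit to only the libraries of a comparison give no value for the difference between times. Of simulated 1.5-fold changes, 28.0% were recovered at 12 h, so many changes of that size may be missed.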

Other observations

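The tests of transcript usage in this part were chosen after the results were seen. Of 27 nucleotide excision repair and translesion polymerase genes, 3 rose with BaP at 12 h and 0 fell, the same counts adjusted over the list alone (camera adjusted p = 0.19, and 0.011 by fry, which does not compare a list with other genes). They were the translesion polymerase POLH (log2 0.81 ± 0.14), DDB2 (0.55 ± 0.11) and XPC (0.51 ± 0.15), which also stand in the p53 list. Of 28 homologous recombination and Fanconi genes, 0 rose and 1 fell (FANCC, -0.83 ± 0.20), also adjusted over the list alone (0 and 1, camera adjusted p = 0.93). Of 10 replication-dependent histone genes, 0 rose and 1 fell (H4C3, -0.86 ± 0.19), again 0 and 1 adjusted over the list alone (camera adjusted p = 0.082). Of 21 other drug metabolism genes, 4 rose and 2 fell (6 and 2 adjusted over the list alone, median 0.22, camera adjusted p = 0.047, and adjusted p = 0.41 with an estimated correlation and 0.1 by fry), with the epoxide hydrolase EPHX1 (0.69 ± 0.11) and the aldo-keto reductase AKR1C3 (0.82 ± 0.15) among the rises. Of 25 unfolded protein response and ATF4 genes, 5 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.88). The cystine transporter SLC7A11 (1.90 ± 0.23), SESN2 (1.02 ± 0.15) and ATF3 (1.38 ± 0.23) rose, and HERPUD1, which acts in degradation at the endoplasmic reticulum, fell by 0.74 on the log2 scale. SLC7A11 also stands in the NRF2 list, SESN2 in the p53 list and ATF3 in the immediate early list. Of 16 heat shock genes, 3 rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.0026, and adjusted p = 0.11 with an estimated correlation): HSPA4L (0.82 ± 0.16), BAG3 (0.58 ± 0.12) and HSPH1 (0.51 ± 0.11). Of 26 hypoxia response genes, 1 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.44), and the glucose transporters SLC2A1 (-1.13 ± 0.15) and SLC2A3 (-0.97 ± 0.14) were among the falls. Of 13 mitochondrially encoded genes, 0 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.017, and adjusted p = 0.56 with an estimated correlation and 0.22 by fry). It was the cytochrome b gene MT-CYB, from 6905 ± 33.2 to 3588 ± 103 CPM. Without BaP 12 h replicate 1 the adjusted p was 0.11 for DDB2, 0.32 for XPC, 0.24 for FANCC, 0.14 for H4C3, 0.16 for BAG3 and 0.096 for HSPH1. Without BaP 12 h replicate 2 it was 0.051 for DDB2, 0.2 for XPC, 0.08 for H4C3 and 0.093 for HSPH1. Without vehicle 12 h replicate 1 it was 0.056 for XPC and 0.096 for HSPH1, and without vehicle 12 h replicate 2 it was 0.072 for DDB2, 0.29 for XPC, 0.075 for FANCC, 0.088 for H4C3 and 0.085 for BAG3. By DESeq2 it was 0.17 for XPC and 0.11 for FANCC, with the GC and mRNA length correction 0.065 for H4C3, and thinned 0.15 for DDB2, 0.14 for XPC, 0.076 for FANCC, 0.076 for HSPA4L and 0.059 for HSPH1.

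The remaining lists at 12 h gave few calls each, some above and some below the 8.25% of all genes tested that passed. Of 22 fatty acid oxidation genes, 1 rose and 1 fell, also adjusted over the list alone (median -0.02 where the mean was 0.02 and camera gave the direction up, adjusted p = 0.85). Of 20 bile acid genes and liver transcription factors, 2 rose and 1 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.2), with the export pump ABCC2 higher (0.95 ± 0.14). ABCC2 also stands in the NRF2 list. Of 13 inflammatory and acute phase genes, 1 rose and 1 fell (2 and 1 adjusted over the list alone, median 0.31, camera adjusted p = 0.02, and adjusted p = 0.21 with an estimated correlation). Of 18 interferon response genes, 1 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.14). Of 35 cytosolic ribosomal protein genes, edgeR called 0 at 12 h and 0 at 24 h, with 0 at an unadjusted p under 0.05 and 0 by DESeq2, and 0 adjusted over the list alone (camera adjusted p = 0.36 and 0.14). Of 3 fibroblast and stellate cell markers, 0 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.31), the growth factor receptor PDGFRB (-0.88 ± 0.16). Of 7 blood and endothelial cell markers, 2 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.19). They were HBA1 (1.16 ± 0.33) and CD14 (1.04 ± 0.31), with an adjusted p of 0.21 and 0.14 without BaP 12 h replicate 1, 0.17 and 0.37 without BaP 12 h replicate 2, 0.096 and 0.14 without vehicle 12 h replicate 1, and 0.18 and 0.17 without vehicle 12 h replicate 2. By DESeq2 it was 0.25 and 0.36, and CD14 also lost the call with no filter (adjusted p = 0.068), with only the libraries of the comparison (0.062) and thinned (0.71).

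At 24 h these lists also gave few calls each, some above and some below the 5.30% of all genes tested that passed. Of 27 nucleotide excision repair and translesion polymerase genes, 3 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.41, and 0.023 by fry), and of 28 homologous recombination and Fanconi genes, 1 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.55). DDB2 was 0.94 ± 0.12 higher and RAD51C 0.91 ± 0.17 on the log2 scale. Of 10 histone genes, 0 rose and 1 fell (H4C3, -1.28 ± 0.23), also adjusted over the list alone (camera adjusted p = 0.12). Of 22 fatty acid oxidation genes, 2 rose and 0 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.37), and of 20 bile acid genes and liver transcription factors, 1 rose and 0 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.36). Of 21 other drug metabolism genes, 4 rose and 1 fell (8 and 2 adjusted over the list alone, camera adjusted p = 0.097), and EPHX1 was among the rises (0.79 ± 0.12). Of 25 unfolded protein response and ATF4 genes, 1 rose and 2 fell (1 and 6 adjusted over the list alone, camera adjusted p = 0.089). Of 16 heat shock genes edgeR called 0, with 5 at an unadjusted p under 0.05, 0 by DESeq2 and 0 adjusted over the list alone (camera adjusted p = 0.19). Of 13 inflammatory genes, 1 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.46), and of 18 interferon response genes, 2 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.49). Of 26 hypoxia response genes, 0 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.097). Of 13 mitochondrially encoded genes, 0 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.26); MT-CYB was the gene (-0.73 ± 0.16). Of 3 fibroblast and stellate cell markers, 1 rose (ACTA2) and 0 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.91, with fry giving the other direction), and of 7 blood and endothelial cell markers, 3 rose and 0 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.2, and 0.023 by fry). They were CD14, CD68 (0.56 ± 0.13) and HBA1 (1.37 ± 0.37), and all lost the call by DESeq2 (adjusted p = 0.075, 0.056 and 0.29). CD68 and HBA1 also lost it without BaP 24 h replicate 2 (0.19 and 0.91), without vehicle 24 h replicate 1 (0.17 and 0.42), without vehicle 24 h replicate 2 (0.16 and 0.094) and with only the libraries of the comparison (0.054 and 0.11), CD14 without vehicle 24 h replicate 1 (0.17) and without vehicle 24 h replicate 2 (0.055), and HBA1 thinned (0.52). The adjusted p of RAD51C and H4C3 was 0.19 and 0.18 without BaP 24 h replicate 2, 0.063 and 0.072 without vehicle 24 h replicate 1, and 0.054 and 0.05 without vehicle 24 h replicate 2. That of MT-CYB was 0.16 without vehicle 24 h replicate 1, 0.14 without vehicle 24 h replicate 2 and 0.11 with only the libraries of the comparison.

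A candidate explanation for the transcript usage calls is an unstable division of reads between near-identical transcripts by RSEM's maximum likelihood estimate. Of the 21 genes called at 12 h, 1 remained with posterior mean counts of the same reads, and 19 had a transcript with under 1 count in each library of 1 group and at least 10 in each library of the other. In METTL7B, ENST00000307755 had 247 and 365 counts with BaP and 4 and 4 with vehicle, while its posterior means were 132 and 205 with BaP and 127 and 106 with vehicle. Usage calls between the vehicle groups of the 2 times numbered 20, against 21 with BaP at 12 h and 63 at 24 h. With posterior mean counts they numbered 4, against 1 and 18. By posterior means 0 of the 21 genes had such an all-or-none transcript, so those changes depend on the estimate used. MAP3K7 was called with both estimates. Its ENST00000369332 had posterior means of 18 and 33 with BaP and 134 and 142 with vehicle. A response to BaP and this instability cannot be told apart from the numbers of calls, and no usage change is read as a response here.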
